A study of Homo sapiens with 8 samples.

How the data were processed

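Gene expression was measured by RNA sequencing in 8 libraries of HaCaT keratinocytes, 4 labelled Control and 4 labelled OGD-R, and samples were grouped by their titles. Per the labels' protocols, libraries were made from total RNA; these protocols name both a NEBNext and a SMARTer kit, and the instrument was an Illumina sequencer. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. The authors deposited 1 table per library with a gene ID, a symbol and a value. The unit is not written in the tables: the deposited values were read as FPKM, because in single-exon genes the lowest values were spaced by a constant divided by the gene's length. The spacing was looked for in 944 single-exon genes. Between 73 and 98 of their values per library were low enough to show it, and between 11 and 19 of these lay within 0.5% of the best step, so the unit rests on few values. This step gave the implied number of fragments per library; if the unit is another length-normalised one, these depths do not hold. FPKM divides by length and by library total, so a gene group that takes a large share of a library lowers all others.

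Of the 24252 rows per table, 4278 carried identifiers of newly assembled genes and 19974 carried Ensembl IDs, all of which were found in GENCODE 29 on GRCh38, 19925 of them with the same symbol. Where IDs share a symbol, lists use the ID with the highest mean over all libraries. Coordinates are those of GENCODE 29, matched by ID. Newly assembled genes took between 1.01% and 1.32% of the summed FPKM, were tested with the rest (145 higher and 33 lower), and are not named. Near-identical gene copies and overlapping genes are uncertain, since how reads were divided among them is not given. No pair of libraries shared more than 1 identical value above 0, so none was counted as a repeat.

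Values were tested as log2(FPKM + 1) with limma (version 3.58.1, R 4.3.3, with an intensity trend) for the 11740 genes with a mean of at least 1 FPKM over all libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low genes. The design had foreseen a count model for counts and this test for normalised values, and the latter was used. Of 32 gene lists fixed before the data were examined, 28 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, two-sided, with an estimated correlation as the alternative; no list passed with the estimated correlation, where the lowest adjusted p was 0.493. The self-contained test fry was also computed, and it did not call several lists that camera called. These were NRF2 and ribosome biogenesis (fry adjusted p = 0.083 each), NF-kB (0.220), G2/M (0.221) and DNA replication (0.468). Histones and epidermal differentiation (0.199 each) and oxidative phosphorylation (0.289) were also among them. It called the chaperone and fatty acid lists, which camera did not (fry adjusted p = 0.0437 and 0.0136). Library shares were compared by exact two-sided permutation.

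Genes were named by a rule fixed before the data were examined. Among genes past the threshold with every OGD-R library on the same side of every Control library, it took the 8 largest increases and decreases and the 4 smallest p-values in each direction. It added up to 4 called members of each list, those in the list's direction first, and fixed genes, among them HIF1A, EPAS1, VEGFA, IL6, TNF, KRT5, KRT14, KRT1 and KRT10. Genes without a symbol were passed over, and some genes that the rule takes are not reported here. Other genes named are said to have been chosen after their values were seen.

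The test was tried on simulated data for the comparison of OGD-R with Control, with 11740 genes, 200 of them changed, in 5 runs. Simulated values were independent between genes and between libraries, so the split that the Controls share across genes was not simulated. With the spread of OGD-R in both groups, 87.8% of 1.5-fold, 97.9% of 2-fold and 100% of 4-fold changes were recovered, and 6.35% of calls were false. With the spread of each group, 45.7%, 69.0% and 88.2% were recovered and 21.1% of calls, 36.4 genes per run, were false. Weighting libraries by group did not lower this share (22.6%). Alternatives covered filters, pseudocounts, each library left out, a replicate block, a residual component and scalings. Pairs of Controls left out, both scalings and the weighting were chosen after seeing the data. Count-based tests and scalings were foreseen but not used here, because the values are not counts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.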

Results

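RNA was sequenced from HaCaT cells, an immortalised line of human skin keratinocytes. Of the 8 libraries, 4 came from Control cells and 4 from cells labelled OGD-R, which had been through oxygen and glucose deprivation followed by return of both and were taken at a stage the labels call early. The duration of deprivation and of return is not given in the sources used here. The series title names a search for a central gene in complex regional pain syndrome, a chronic pain disorder of a limb, so genes of hypoxia, stress, inflammation and pain signalling were among those examined. Each library held FPKM values for 24252 genes, of which between 17188 and 18170 were above 0. The summed FPKM lay between 428984 and 475385. From the spacing of the lowest values, 1 fragment on a transcript of 2000 bases was worth between 0.0201 FPKM (Control 1) and 0.0297 FPKM (Control 4), so Control 1 was the deepest and Control 4 the shallowest library. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

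The OGD-R libraries lay close together, whereas the Control libraries fell in 2 places. Across the 11740 genes tested, log2 values correlated between 0.992 and 0.993 among the OGD-R libraries. Control 1 and Control 2 correlated at 0.992, and Control 3 and Control 4 at 0.991. Correlations between Controls 1 and 2 and Controls 3 and 4 lay between 0.874 and 0.881, below those of Controls 1 and 2 with OGD-R (0.940 to 0.947). These correlations run across genes, which are not independent replicates. The median SD of log2 values was 0.29 in Control and 0.09 in OGD-R. Cell cycle genes, chosen after their values were seen, show the size of the split. CDK1, a kinase that drives entry into mitosis, was at 61.7 and 73.3 FPKM in Controls 1 and 2, at 4.81 and 2.79 FPKM in Controls 3 and 4, and at 46.6 ± 0.901 FPKM (SD, n = 4) in OGD-R. ATF3, a stress-induced transcription factor, was at 5.01, 3.41, 147 and 139 FPKM in Controls 1 to 4 and at 3.72 ± 0.592 FPKM (SD, n = 4) in OGD-R. Values of all 4 Controls are therefore given for several of the genes and groups that this split touches, and for others the values with a pair of Controls left out. In such a fit the Controls kept correlate at 0.992 or 0.991. Its p-values rest on the spread within that pair and within OGD-R, which may be technical.

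**Figure D1:**
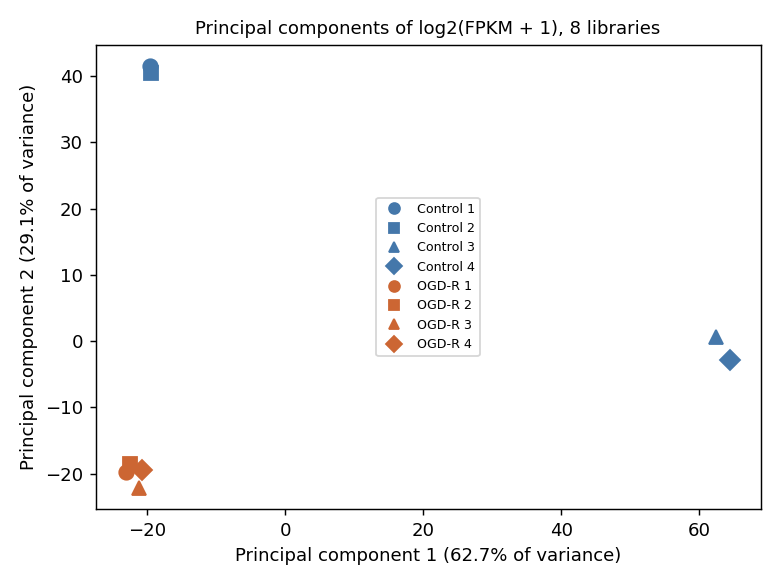
Principal components of log2(FPKM + 1) over the 11740 genes tested, with 1 point per library; the horizontal axis is component 1 (62.7% of variance) and the vertical axis component 2 (29.1%). Controls 3 and 4 lie at 62.4 and 64.5 on component 1 while the other 6 libraries lie below 0, and on component 2 Controls 1 and 2 lie at 41.6 and 40.5.

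OGD-R cells had more RNA of several keratin and epidermal differentiation genes and less RNA of matrix, interleukin 1 and immediate early genes than Control cells. FKBP5, a co-chaperone of steroid receptors, was at 57.0 ± 0.605 FPKM in OGD-R against 10.9 ± 0.538 FPKM in Control (SD, n = 4 each), the smallest p of all genes. SULT1E1, the estrogen sulfotransferase, was at 42.3 ± 4.77 FPKM against 1.18 ± 0.998 FPKM. SERPINE2, a secreted inhibitor of serine proteases, was at 4.60 ± 0.668 FPKM in OGD-R against 54.9 ± 6.63 FPKM in Control. FOSL1, an AP-1 transcription factor, was at 28.8 ± 1.53 FPKM against 216 ± 39.5 FPKM. Of 11740 genes tested with limma on log2(FPKM + 1), 1202 were higher and 1138 lower in OGD-R at a Benjamini-Hochberg adjusted p of 0.05. An absolute log2 fold change of at least 1 was reached by 271 of the higher and 238 of the lower genes. Every OGD-R library lay above every Control library for 1193 of the higher genes, and below for 1132 of the lower genes. Called or not, 1789 genes lay wholly above and 1737 wholly below, where chance would separate 2.86% of the 11740 tested if libraries were independent. Libraries that lie as close together as those of OGD-R can separate many genes for any reason, so this contrast does not measure an effect of the treatment.

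The largest increases included SULT1E1, KRT4, KRT1, SEMA6D, ALPG, KRT15 and ATP6V1B1. SULT1E1 (ENSG00000109193, chromosome 4, 69841212 to 69860152, minus strand, GRCh38) had a log2 fold change of 4.43 ± 0.31 (SE; limma adjusted p = 0.000107). The keratins KRT4, of mucosal epithelium, and KRT1, of suprabasal epidermis, had log2 fold changes of 4.15 ± 0.88 (SE; limma adjusted p = 0.0141) and 3.66 ± 0.59 (SE; limma adjusted p = 0.00436). KRT4 was at 6.68, 5.52, 88.1 and 75.5 FPKM in Controls 1 to 4, so its log2 fold change was 5.92 without Controls 3 and 4 and 2.37 without Controls 1 and 2. KRT1 (ENSG00000167768) lies on chromosome 12, 52674736 to 52680407, minus strand. It was at 6.33, 4.64, 31.8 and 29.7 FPKM in Controls 1 to 4 and at 181 ± 30.7 FPKM (SD, n = 4) in OGD-R. KRT15, a basal keratin, was at 636 ± 42.6 FPKM in OGD-R against 84.5 ± 33.2 FPKM in Control (SD, n = 4 each). SEMA6D, a semaphorin, was at 12.8 ± 1.26 FPKM against 0.343 ± 0.229 FPKM. ALPG is nearly identical to other alkaline phosphatase genes, so its log2 fold change of 3.02 is uncertain. FKBP5 (ENSG00000096060, chromosome 6, 35573585 to 35728583, minus strand) had a log2 fold change of 2.29 ± 0.07 (SE; limma adjusted p = 1.07e-05). VGLL1, a cofactor of TEAD transcription factors, and ALDH1A1, a retinaldehyde dehydrogenase, were, with FKBP5 and SEMA6D, the named increases of smallest p, with log2 fold changes of 2.41 and 2.06.

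The largest decreases were in MMP1, HSPA6, CSF2, SERPINE2, IL1A, PHLDA1, UPP1 and INHBA. MMP1, the interstitial collagenase (ENSG00000196611, chromosome 11, 102789920 to 102798160, minus strand), fell by 4.60 on the log2 scale (SE 0.922; limma adjusted p = 0.0112). It was at 15.4, 12.6, 199 and 185 FPKM in Controls 1 to 4 and at 1.23 ± 0.337 FPKM (SD, n = 4) in OGD-R. SERPINE2 (ENSG00000135919, chromosome 2, 223975112 to 224039319, minus strand) fell by 3.32 on the log2 scale (SE 0.125; limma adjusted p = 1.46e-05), with Controls between 46.9 and 60.4 FPKM. HSPA6, an inducible HSP70, fell by 3.42 from a Control mean of 11.6 ± 5.002 FPKM (SD, n = 4). IL1A, the interleukin 1 alpha gene, fell by 3.28 from 11.6, 15.7, 83.9 and 80.3 FPKM in Controls 1 to 4. MMP2, the gelatinase A gene, and SERINC2 also had small p-values and fell by 2.20 and 1.51 on the log2 scale.

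**Figure D2:**
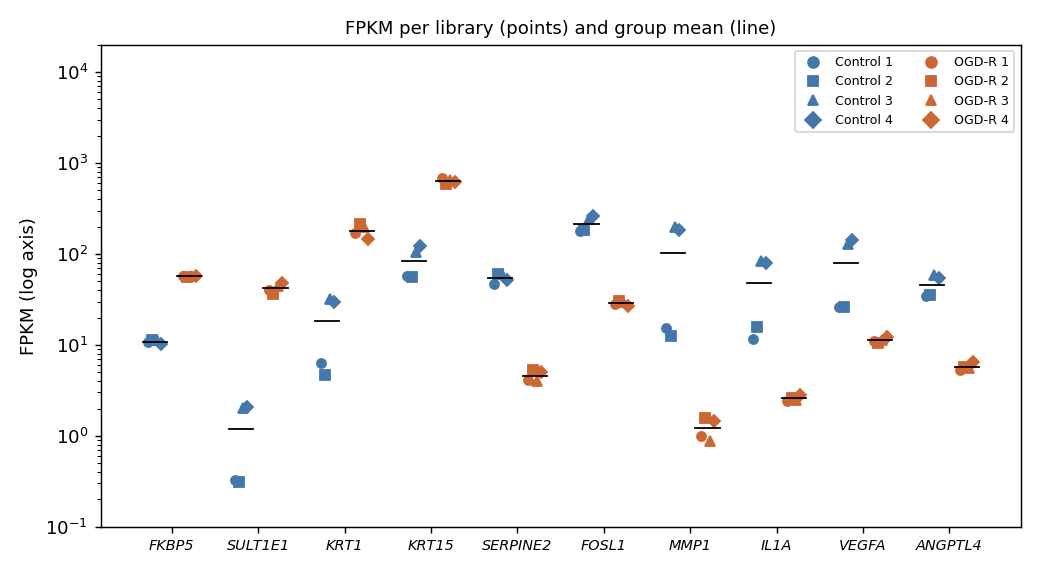
FPKM on a log axis of 10 genes in each library, as points, with the mean of the 4 Control and the 4 OGD-R libraries as lines. FKBP5 lies at 57.0 FPKM on average in OGD-R against 10.9 FPKM in Control, and VEGFA lies at 25.8, 25.8, 128 and 142 FPKM in Controls 1 to 4, above all OGD-R libraries.

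Matrix, stress response and mitochondrial genes kept their direction and call with either pair of Controls left out, but the size of the change depended on the pair. The median log2 fold change without Controls 3 and 4 was -0.76 for the matrix list, -0.40 for the stress response list and 0.37 for the mitochondrial list, and without Controls 1 and 2 it was -2.23, -1.43 and 0.64. The mean log2 value of the stress response list was 4.70, 4.76, 5.97 and 5.85 in Controls 1 to 4. Of 28 measured matrix remodelling, TGF-beta and wound migration genes, 15 fell and 0 rose (18 lower when adjusted over the list alone; camera adjusted p = 5.01e-09, and adjusted p = 0.493 with an estimated correlation). FN1, the fibronectin gene, fell by 2.57 on the log2 scale from 239, 265, 1511 and 1385 FPKM in Controls 1 to 4, and INHBA, the activin A subunit, fell by 2.94. Of 28 integrated stress response genes, targets of the transcription factor ATF4, 11 fell and 0 rose (16 lower when adjusted over the list alone; camera adjusted p = 9.83e-08, and adjusted p = 0.493 with an estimated correlation). TRIB3, a pseudokinase, was at 41.7, 37.2, 214 and 175 FPKM in Controls 1 to 4 against 16.8 ± 1.06 FPKM (SD, n = 4) in OGD-R. STC2, a secreted glycoprotein, and SLC7A11, the cystine transporter, fell by 1.46 and 1.41 on the log2 scale. Of 13 messenger RNAs encoded in mitochondria, 8 rose and 0 fell (11 higher when adjusted over the list alone; camera adjusted p = 8.87e-05, and adjusted p = 0.493 with an estimated correlation). MT-CO2 and MT-CO3, subunits of cytochrome c oxidase, had log2 fold changes of 0.95 and 0.88.

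Immediate early and cytokine genes were called lower in OGD-R as lists, and both calls were lost without Controls 3 and 4. Of 25 immediate early genes 7 fell and 0 rose (14 lower when adjusted over the list alone; camera adjusted p = 4.00e-06, and adjusted p = 0.696 with an estimated correlation). PHLDA1 fell by 3.08, FOSL1 by 2.84, IER3 by 2.38 and DUSP4 by 1.92 on the log2 scale. The mean log2 value of the immediate early list was 3.78, 3.84, 5.58 and 5.58 in Controls 1 to 4, and without Controls 3 and 4 its camera adjusted p was 0.0811. The median log2 fold change of this list was then -0.38 against -1.33 with all libraries, with 5 members higher and 14 lower. Of 23 NF-kB driven cytokine and inflammation genes 3 fell and 0 rose (3 lower when adjusted over the list alone; camera adjusted p = 0.000388, and adjusted p = 0.726 with an estimated correlation). These were CSF2, whose call was lost when any single OGD-R library was left out, IL1A and IL1B; IL1B was at 19.3, 19.2, 71.0 and 69.4 FPKM in Controls 1 to 4 and at 6.04 ± 0.669 FPKM (SD, n = 4) in OGD-R. The mean log2 value of the cytokine list was 1.90, 2.02, 4.46 and 4.39 in Controls 1 to 4. Of its members 5 were higher and 6 lower without Controls 3 and 4 (median -0.05 against -1.23 with all libraries, camera adjusted p = 0.998). IL6 and TNF did not pass the test (limma adjusted p = 0.194 and 0.202). IL6 was at 0.209, 0.233, 5.27 and 5.72 FPKM in Controls 1 to 4 and at 0.208 ± 0.0271 FPKM (SD, n = 4) in OGD-R. Of 20 pain mediators and receptors 3 rose and 3 fell (3 and 3 when adjusted over the list alone; camera adjusted p = 0.336). NTF4, a neurotrophin, had a log2 fold change of 1.20, and F2RL1, the protease-activated receptor 2 gene, fell by 1.31.

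Targets of hypoxia-inducible factor, the transcription factor stabilised by low oxygen, were not raised as a list in OGD-R. Of 27 measured targets 1 rose and 6 fell (1 and 7 when adjusted over the list alone; camera adjusted p = 0.0317, and adjusted p = 0.493 with an estimated correlation). ANGPTL4, a lipase inhibitor, fell by 2.76 on the log2 scale, with 34.7, 35.3, 58.9 and 54.4 FPKM in Controls 1 to 4 and 5.75 ± 0.524 FPKM (SD, n = 4) in OGD-R. VEGFA, the angiogenic growth factor gene, fell by 2.30 (SE 0.583; limma adjusted p = 0.0279), a call lost when any single OGD-R library was left out, and HK2, a hexokinase, fell by 1.27. Without Controls 3 and 4, 8 of the targets were higher and 10 lower, the same 6 among them (median -0.12 against -0.09 with all libraries, adjusted p = 0.761), and without Controls 1 and 2, 6 were higher and 16 lower (adjusted p = 0.00587). The call was also lost when Control 3 alone or Control 4 alone was left out. The targets CA9, EGLN3 and ENO2 were too low to be tested. CA9 was at 0.587, 0.263, 0.265 and 0.130 FPKM in OGD-R 1 to 4 and at 0.0217, 0.0506, 0 and 0 FPKM in Controls 1 to 4. EGLN3 and ENO2 overlapped between the groups. HIF1A fell by 0.48 (SE 0.0872; limma adjusted p = 0.00756), while EPAS1, which encodes the related HIF-2 alpha, was at 18.5 ± 0.409 FPKM against 18.1 ± 6.05 FPKM (SD, n = 4 each; limma adjusted p = 0.814). With 12.7, 13.1, 22.8 and 23.9 FPKM in Controls 1 to 4, EPAS1 was called in opposite directions, with a log2 fold change of 0.49 without Controls 3 and 4 (limma adjusted p = 0.000177) and of -0.32 without Controls 1 and 2 (limma adjusted p = 0.00158). Of 16 glycolysis enzymes 1 rose and 2 fell (1 and 2 when adjusted over the list alone; camera adjusted p = 0.768), namely ALDOC, HK2 and PFKP. The median log2 fold change of this list was 0.12 and its mean -0.01, between opposite results: without Controls 3 and 4, 12 enzymes were lower and 1 higher (median -0.39, adjusted p = 0.00126), and without Controls 1 and 2, 13 were higher and 3 lower (median 0.57, adjusted p = 0.0468).

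Antioxidant, iron and ribosome biogenesis genes were called lower in OGD-R as lists with all libraries, but each call depended on which Controls were kept. Of 22 NRF2 antioxidant genes 2 rose and 7 fell (2 and 9 when adjusted over the list alone; camera adjusted p = 0.00234, and adjusted p = 0.701 with an estimated correlation). HMOX1, heme oxygenase 1, was at 1.58 ± 0.211 FPKM against 8.67 ± 1.28 FPKM (SD, n = 4 each). FTL, the ferritin light chain, fell by 1.88 and AKR1C1 by 1.70 on the log2 scale; pseudogenes or near-identical copies of both make these values uncertain. AKR1C1 was at 18.7, 18.5, 4.28 and 3.58 FPKM in Controls 1 to 4, so its log2 fold change was -2.70 without Controls 3 and 4 and -0.71 without Controls 1 and 2. Of 17 ferroptosis and iron handling genes 7 fell and 0 rose (2 higher and 8 lower when adjusted over the list alone; camera adjusted p = 0.0132, and adjusted p = 0.493 with an estimated correlation). Of 23 ribosome biogenesis genes, among them UTP4 and RRP12, 7 fell and 0 rose (9 lower when adjusted over the list alone; camera adjusted p = 0.000111, and adjusted p = 0.696 with an estimated correlation). Of 23 p53 targets 2 rose and 4 fell (2 and 5 when adjusted over the list alone; camera adjusted p = 0.0442, and adjusted p = 0.609 with an estimated correlation); AEN, a nuclease, fell by 1.33. The NRF2 and ribosome biogenesis calls were lost without Controls 1 and 2 (adjusted p = 0.366 and 0.226), and the iron and p53 calls without Controls 3 and 4 (adjusted p = 0.147 and 0.998). The median of the iron list was then -0.34 against -0.32 with all libraries, with 5 members higher and 10 lower. The same 7 genes were among the lower ones, which their selection nearly fixed in advance. For the p53 list the median was -0.08 against -0.33, with 7 members higher and 9 lower. Without Controls 1 and 2 the NRF2 median was -0.08 against -0.56 with all libraries, with 7 members higher and 9 lower. That of ribosome biogenesis was 0.005 against -0.31, with 5 members higher and 9 lower.

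Interferon genes were higher in OGD-R, and epidermal differentiation genes as a list were higher than in Controls 1 and 2 but not than in Controls 3 and 4. Of 22 epidermal differentiation genes 4 rose and 0 fell (4 higher when adjusted over the list alone; camera adjusted p = 0.0315, and adjusted p = 0.732 with an estimated correlation). These were KRT1, DSG1, TGM1 and GRHL3. GRHL3, a transcription factor of the epidermal barrier, was at 16.4 ± 1.65 FPKM against 5.66 ± 0.300 FPKM (SD, n = 4 each). KRT10, the partner of KRT1, was at 29.98, 27.6, 285 and 259 FPKM in Controls 1 to 4 and at 467 ± 48.9 FPKM (SD, n = 4) in OGD-R, and did not pass the test (limma adjusted p = 0.0718). The mean log2 value of the epidermal list was 2.36, 2.32, 4.94 and 4.96 in Controls 1 to 4 and lay between 4.22 and 4.44 in OGD-R. Without Controls 1 and 2, 7 members were higher and 11 lower (median -0.49, adjusted p = 0.0663). Scaled without mitochondrial genes the epidermal list was not called. Of 21 type I interferon response genes 5 rose and 0 fell (7 higher when adjusted over the list alone; camera adjusted p = 0.00382, and adjusted p = 0.493 with an estimated correlation). IFIT3 had a log2 fold change of 0.97 and OAS1, which makes an RNase L activator, of 0.79. Without Controls 1 and 2 the adjusted p of the interferon list was 0.170. Its median log2 fold change was then 0.28 against 0.42 with all libraries, with 11 members higher and 3 lower. Of 18 basal keratinocyte and hemidesmosome genes 6 rose and 7 fell (7 and 8 when adjusted over the list alone; camera adjusted p = 0.768). The basal keratins KRT5 and KRT14 had log2 fold changes of 1.01 and 0.41, while LAMA3 and LAMB3, which encode laminin chains, fell by 2.13 and 1.03. Of 13 wound and stress keratins and alarmins 2 fell and 0 rose (3 lower when adjusted over the list alone; camera adjusted p = 0.155), namely S100A2 and KRT6A, the latter with near-identical copies.

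Cell cycle lists were called higher in OGD-R, but their values followed the split among Controls. Of 26 G2/M and mitosis genes 0 rose and 0 fell (0 when adjusted over the list alone; camera adjusted p = 0.000364, and adjusted p = 0.732 with an estimated correlation). The mean log2 value of this list was 5.37, 5.47, 2.40 and 2.35 in Controls 1 to 4 and lay between 5.34 and 5.47 in OGD-R. Without Controls 3 and 4 its adjusted p was 0.761. Of 28 DNA replication genes 1 rose, E2F2, and 0 fell (0 when adjusted over the list alone; camera adjusted p = 0.0288, and adjusted p = 0.778 with an estimated correlation). Without Controls 3 and 4 the replication list turned, with 26 members lower and a median of -0.54 (adjusted p = 5.43e-07). Of 28 nuclear genes of oxidative phosphorylation 2 rose, NDUFA1 and UQCRC2, and 0 fell (0 when adjusted over the list alone; camera adjusted p = 0.0032, and adjusted p = 0.732 with an estimated correlation), and the median was -0.04 without Controls 3 and 4. Of 11 replication-dependent histone genes 1 rose, HIST1H2BJ, and 0 fell (1 higher when adjusted over the list alone; camera adjusted p = 0.0496, and adjusted p = 0.726 with an estimated correlation). The histone median was -0.17 without Controls 1 and 2, with 2 members higher and 4 lower (camera adjusted p = 0.212). It was 1.11 without Controls 3 and 4, with 11 members higher and 0 lower (camera adjusted p = 1.74e-06). Scaled without mitochondrial genes neither the replication list nor the histone list was called.

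**Figure D3:**
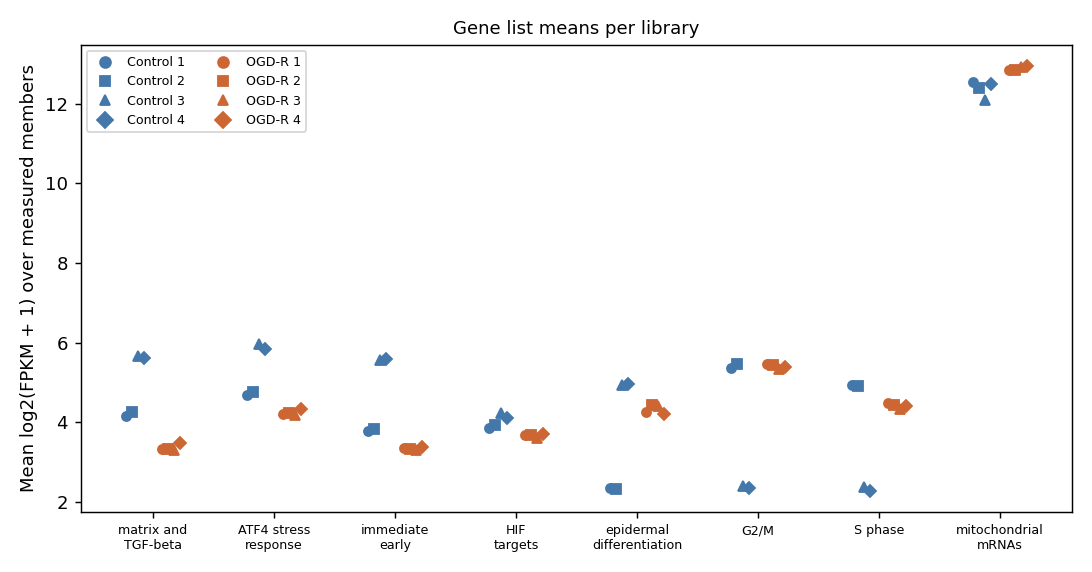
Mean log2(FPKM + 1) over the measured members of 8 gene lists, with 1 point per library. In the G2/M list Controls 3 and 4 lie at 2.40 and 2.35 while Controls 1 and 2 lie at 5.37 and 5.47, and the OGD-R libraries lie between 5.34 and 5.47.

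The remaining lists were not called with all 8 libraries, though several were with a pair of Controls left out. Of 20 endoplasmic reticulum chaperones 2 rose, CALR and HSP90B1, and 2 fell, EDEM1 and CANX (2 and 2 when adjusted over the list alone; camera adjusted p = 0.132). Of 18 heat shock factor genes 1 rose, HSPA4L, and 2 fell, CRYAB and BAG3 (1 and 3 when adjusted over the list alone; adjusted p = 0.108). Of 24 apoptosis regulators 2 rose and 4 fell, PMAIP1, BIK, BID and BAK1 (3 and 4 when adjusted over the list alone; adjusted p = 0.513). Of 24 autophagy and lysosome genes 1 rose, CTSD, and 2 fell, SQSTM1 and CTSL (0 and 1 when adjusted over the list alone; adjusted p = 0.0760). Of 25 cholesterol synthesis genes 1 rose and 0 fell (1 higher when adjusted over the list alone; adjusted p = 0.789). Of 14 fatty acid synthesis genes 3 fell, FASN, ACLY and ELOVL5, and 0 rose (3 lower when adjusted over the list alone; adjusted p = 0.108). Of 17 tricarboxylic acid cycle enzymes 0 rose and 0 fell (0 when adjusted over the list alone; adjusted p = 0.155). Of 34 ribosomal protein genes 1 rose and 0 fell (0 when adjusted over the list alone; adjusted p = 0.356). Without Controls 3 and 4, 15 of the heat shock factor genes were lower (adjusted p = 0.00023) and 15 of the cholesterol synthesis genes higher (adjusted p = 0.000419). Without Controls 1 and 2, 17 of the cholesterol synthesis genes were lower (adjusted p = 0.000316), 13 of the autophagy and lysosome genes lower (adjusted p = 0.000221), and 14 of the tricarboxylic acid cycle enzymes higher (adjusted p = 0.000623). The chaperone and fatty acid lists were then also called lower (adjusted p = 0.0446 and 0.0305), as was the pain list (adjusted p = 0.00587). Wound and stress keratins and alarmins were called higher without Controls 3 and 4 (adjusted p = 0.0101) and lower without Controls 1 and 2 (adjusted p = 8.00e-06). Lists of fibroblast, melanocyte, immune and endothelial markers had 3, 1, 1 and 0 members at a mean of 1 FPKM or more and were too small to test. Among these, MITF rose by 0.50 on the log2 scale and CD68, a lysosomal protein gene, fell by 1.81. The fibroblast markers POSTN and FAP, chosen after their values were seen, were at 11.04 and 6.83 FPKM in Control 3, at 12.9 and 7.66 FPKM in Control 4, and at most at 1.43 FPKM in any other library.

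Mitochondrially encoded genes took 27.9 ± 1.02% of the summed FPKM in OGD-R against 20.2 ± 1.94% in Control (SD, n = 4 each), higher in 4 of 4 OGD-R libraries. The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 libraries allow, and 0.0857 after adjustment over 6 shares, so no share passed. The 100 most abundant genes took 47.3 ± 0.651% against 42.3 ± 1.61% (SD, n = 4 each; exact permutation p = 0.0286, adjusted 0.0857). Ribosomal protein genes took 5.08% against 5.15% (adjusted exact permutation p = 0.651) and histone genes 0.0411% against 0.0383% (adjusted exact permutation p = 0.657). The adjusted exact permutation p was 0.171 for the summed FPKM and 0.114 for the number of genes above 0.

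The number of genes called depended on which libraries and which scaling were used. Scaled to the total without mitochondrial genes, 1589 genes were higher and 870 lower. Without Controls 3 and 4 there were 2673 higher and 3807 lower genes, and without Controls 1 and 2 there were 4603 and 3337. Each of these fits keeps a pair of Controls that lie close together. Their p-values rest on that small spread, so their counts are not comparable with those of all libraries. These fits called 1780 genes in opposite directions, none of them among the 2340 called with all libraries. Among the 2340, 1191 higher and 1130 lower genes were called the same way with all libraries and with either pair of Controls left out. Selection against the full spread of the Controls nearly fixed this in advance, so it does not show that the calls are stable. Of the 2340, 2059 kept their call with the scaling without mitochondrial genes, and 1373, 1308, 1255 and 1318 without OGD-R 1, 2, 3 and 4. Leaving out OGD-R 1, 2, 3 or 4 gave 720, 730, 700 and 702 higher genes and 669, 586, 565 and 630 lower genes. On simulated values with the spread of each group, 21.1% of the calls were false against a target of 5%. The simulation changed 200 genes and left out the split that the Controls share across genes. Its share of false calls therefore does not carry over to the 2340 genes called, whose share of false calls is not known. Of 35 ways to split the 8 libraries 4 against 4, 11 called at least 16 lists, the real grouping with its 16 among them, so the number of lists called does not set the groups apart from other splits.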

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

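All tests of the explanations weighed here were chosen after the results were seen, except the counts over other splits of the libraries. In 266 groups of 4 values looked at, 6 held a library far from the other 3, or 2.26% where chance gives about 5% for independent values. The rule cannot flag values that fall into pairs, as those of the Controls often do, so the low share does not show that replicates are alike. CANX was at 7.57 on the log2 scale in Control 3, against 7.47 to 7.48 in the other Controls (gap over range 0.939). NTF4 was at 1.94 in Control 4 against 2.40 to 2.47 (0.862). PLEC was at 5.03 in OGD-R 1 against 4.80 to 4.84 (0.841). FN1 was at 7.02 in OGD-R 4 against 6.55 to 6.56 (0.963). The histone share was 0.0419% in OGD-R 4 against 0.0408% to 0.0409% (0.840), and the ribosome biogenesis mean was 4.91 in OGD-R 3 against 5.01 to 5.03 (0.842).

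The real grouping called 2340 genes, it was the only 1 of 35 splits to call as many, and the highest other split called 1 gene. Every other split puts OGD-R libraries, which correlated between 0.992 and 0.993, on both sides. Low counts in the other splits were thus largely fixed in advance, and the gene count cannot exclude chance or a batch. Nor can the number of gene lists: the real grouping called 16, the highest other split 20, and 11 of 35 splits, the real one included, called as many.

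Controls 3 and 4 stood apart from Controls 1 and 2. A swap of labels between single libraries of the groups is argued against. The lowest correlation between OGD-R libraries exceeded the highest between OGD-R and Control by 0.0449. An exchange of the group labels as a whole would leave these correlations unchanged, so they cannot test it. A scaling difference would leave the correlation over genes nearly unchanged and is argued against by the highest correlation across the split, 0.881; a difference in depth is argued against because Controls 3 and 4, whose depths differ 1.29 times, correlated more closely by 0.111 than Controls 2 and 3, whose depths differ 1.09 times. RNA from fibroblasts is argued against because only 3 of 12 fibroblast markers, COL1A1, POSTN and FAP, reached 1 FPKM in both libraries, while COL3A1 was at 0.0284 and 0.0647 FPKM; of 29 markers of melanocytes, immune and endothelial cells 2 did, MITF and CD68. A different culture condition, a separate batch or samples from outside these groups remain open (the value column of Control 3 is headed C3, unlike those of the other Controls, which does not decide it), and no biological explanation was tested because the labels give none within Control.

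Targets of hypoxia-inducible factor were lower in OGD-R as a list. Controls 3 and 4 may set the list's call, since the adjusted p was 0.761 without them and 0.00587 without Controls 1 and 2. With Controls 3 and 4 left out all 6 targets called lower stayed so. Their selection nearly fixed this in advance, since 2322 of all 2340 genes called also kept their call. The log2 fold change of VEGFA went from -2.30 to -1.13 and that of HK2 from -1.27 to -0.84. ANGPTL4 went from -2.76 to -2.42 and STC2 from -1.46 to -1.54. Over the 27 targets the median was then -0.12 and the mean -0.23 (SD 0.749), against -0.09 and -0.37 (SD 0.793) with all libraries. A hypoxic response that had ended by harvest cannot be told apart from none: 1 of 27 targets was called higher, 8 were without Controls 3 and 4, and no time or hypoxic group was given to decide it.

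Some abundant genes jumped between OGD-R libraries. Among 5646 genes with an OGD-R mean of at least 10 FPKM, 16 differed by more than 2.5 times between the highest and lowest OGD-R library. SENP3-EIF4A1, for example, was at 189 FPKM in OGD-R 3 and at 1.24 FPKM in OGD-R 1. Reads shared with an overlapping gene model are a candidate explanation: 11 of the 16 shared exon sequence with another gene on the same strand, against 17.4% of the others (odds ratio 10.4; Fisher's exact p = 8.72e-06, two-sided). Over 9 pairs of limits the odds ratio lay between 5.06 and 27.3. The other 5, ATP5F1A among them, had no such overlap, and nothing tested accounts for them.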

How the results depend on the processing

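Scalings, pairs of Controls left out and weighting by group were chosen after the data were seen, the other settings before; planned settings for counts were not run, because the values are not counts. Higher genes (1202) numbered 689 at a mean of 5 FPKM, 271 at an absolute log2 fold change of 1, 551 at an adjusted p of 0.01 and 3672 with the first residual component; lower genes (1138) numbered 238, 427 and 3408 under the last 3. Leaving out 1 library gave 700 to 1448 higher and 565 to 1321 lower genes. Without Controls 3 and 4 there were 2673 and 3807, without Controls 1 and 2 there were 4603 and 3337. The Controls kept in each of these fits lie close together, so these counts are not comparable with the others. The replicate number as a block gave 625 higher, 507 lower, 7 higher lists and 9 lower lists; numbers did not pair libraries (correlations of deviations 0.0450 to 0.0646, own number best for 1 of 4). Of 2340 genes called, 2158 kept their call with median-ratio scaling, 1723 weighted by group, and none was called the opposite way in any setting. For the fits with a pair of Controls left out, selection nearly fixed this in advance. Lists higher (7) numbered 0 with an estimated correlation and 3 scaled without mitochondrial genes, where the mitochondrial list is not tested and DNA replication, histones and epidermal differentiation lost their calls; lists lower (9) numbered 0 and, with the residual component, 14. Leaving out 1 library moved the summed FPKM difference between 15597 and 30979 and that of the 100 most abundant genes between 4.57 and 5.71 percentage points. The direction given by camera turned in 8 lists that were called before or after. Without Controls 1 and 2 their medians were 0.57 for glycolysis (0.12 with all libraries, and -0.39 without Controls 3 and 4), -0.17 for histones and -0.49 for epidermal differentiation, and EPAS1 was at -0.32 (0.49 without Controls 3 and 4). Without Controls 3 and 4 the medians were -0.0468 for NF-kB genes, -0.54 for DNA replication, 0.52 for wound keratins, 0.31 for cholesterol synthesis and -0.0444 for oxidative phosphorylation; the cause was not tested. CSF2 and VEGFA lost their calls without any single OGD-R library. In Control 4, the shallowest library, 0.0297 FPKM on a transcript of 2000 bases rests on about 1 fragment.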

Other observations

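The gene groups and tests in this part were chosen after the data were seen, so their p-values are not independent evidence. Genes that respond to bone morphogenetic proteins were higher in OGD-R: 5 of 6 measured members rose and 0 fell (camera p = 1.04e-05, and p = 0.00402 with an estimated correlation, neither adjusted for the choice). ID2, an inhibitor of helix-loop-helix transcription factors, was at 36.3 ± 4.00 FPKM against 7.48 ± 1.86 FPKM, and SMAD6, an inhibitor of the pathway, at 5.45 ± 0.748 FPKM against 1.30 ± 0.185 FPKM (SD, n = 4 each). ID1, ID3 and ID4 also rose, and SMAD7 did not pass the test. Among 10 keratins outside the fixed lists 4 rose, KRT4, KRT13, KRT19 and KRT77, and 1 fell, KRT18, so that the group as a whole was not higher (camera p = 0.569, and p = 0.761 with an estimated correlation, neither adjusted for the choice). KRT13, a mucosal keratin, was at 71.1, 60.8, 303 and 297 FPKM in Controls 1 to 4 and in the OGD-R libraries at 844 ± 76.0 FPKM (SD, n = 4).

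Ligands of the EGF receptor were lower in OGD-R as a group (camera p = 0.00116, and p = 0.0271 with an estimated correlation). Of 5 measured members 3 fell, AREG, EREG and TGFA, and 0 rose. HBEGF and EPGN, with log2 fold changes of -2.96 and 0.85, did not pass the test (limma adjusted p = 0.0507 and 0.260). In Controls 1 to 4 AREG was at 37.4, 44.9, 117 and 135 FPKM and HBEGF at 9.79, 11.4, 133 and 136 FPKM. EPGN was at 5.495, 6.43, 0.598 and 1.04 FPKM there and at 5.40 ± 0.441 FPKM (SD, n = 4) in OGD-R. A hypothesis is lower ERK output in OGD-R, raised by PHLDA1, SPRY2, SPRY4, DUSP4 and DUSP6, which had been called lower in the immediate early list. Among the 5 other ERK output genes measured, 2 were called lower, ETV4 and ETV5, and 0 higher, while CCND1, EPHA2 and EPHA4 did not pass the test. This leaves lower ERK output open, since the genes are few and no ERK activity was measured.

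FKBP5 had the smallest p of all genes, which raised the hypothesis of a glucocorticoid response. Among 7 other glucocorticoid-induced genes measured, 2 were called higher, TSC22D3 and KLF9, and 2 lower, MT2A and ERRFI1, while PER1, DUSP1 and SGK1 did not pass the test. For these last genes every OGD-R library lay above Controls 1 and 2 and below Controls 3 and 4. ZBTB16 and CRISPLD2 were too low to be tested. ZBTB16 lay between 0.446 and 0.496 FPKM in OGD-R and at most at 0.0153 FPKM in Control, and CRISPLD2 overlapped between the groups. The limits of the glucocorticoid test were changed after its result was seen. An earlier limit, by which 2 or more lower genes argue against the hypothesis, would have done so here. The hypothesis is left undecided.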
